A study of Homo sapiens with 6 samples.

How the data were processed

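Small RNA libraries were made from exosomes, the small vesicles that cells release into their medium, of H1299 cells, an established line of human non-small cell lung cancer. Per the labels, cells stably expressed either a control short hairpin RNA or one against WDR4, the non-catalytic partner of METTL1 in the enzyme that places 7-methylguanosine on RNA. They were kept for 48 hours in medium freed of exosomes before collection. Each group had 3 libraries from separate biological repeats per the labels, 6 in all, prepared by ligation of adaptors to both RNA ends, amplification and size selection.

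The deposited workbook held 1 count column per group. Per the file headers, each column joined the 3 libraries of its group, and its values were whole-number read counts per mature miRNA that the authors had not normalized. No value per library was used here, so the spread between the 3 repeats is unknown and every group value below is the authors' pooled value. FastQC, Trim Galore, Bowtie, SAMtools and edgeR are named by the submitters' processing notes, without a role or a version. The genome build, the miRNA annotation, the treatment of reads that match several miRNAs and whether molecular identifiers were collapsed are not given in the sources used here.

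The authors' deposited table also gave, per the file headers, a log2 fold, a normalized log2 fold, a z-score, a p-value and 2 q-values per miRNA. Recomputation from the deposited counts showed that the log2 fold was control over shWDR4, so a positive value means a lower count in shWDR4. The normalized log2 fold in the authors' deposited table subtracted 0.88, the log2 of the ratio of the 2 column totals. A count of 0 entered the authors' deposited table as 0.5, and no fold was given for 320 of the 1247 entries, whose counts did not exceed 4 in either column. The significance mark matched a Storey q-value under 0.001 together with a 2-fold normalized difference in all 1247 entries of the authors' deposited table. The deposited score of each miRNA was the z-score of the authors' comparison, per the file headers, and was deposited without its formula. These deposited p-values and q-values belong to 2 pooled columns, which hold no spread between repeats. The deposited enrichment tables gave p-values, adjusted p-values and gene counts per term, with no statement of how the gene list was chosen.

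Counts were divided by their column total and multiplied by 1000000 to give CPM, and the fold was shWDR4 over control unless stated otherwise. Shares and folds carry 95% exact (Clopper-Pearson) intervals, for folds conditional on the sum of both counts. All intervals and floors cover counting error only, since amplified reads are not independent molecules. The control column held 1020282 counts and the shWDR4 column 552913, so a count of 0 allows up to 3 counts, or 2.94 CPM in control and 5.43 CPM in shWDR4. For the size rule and the ranks, 3 counts over the group stand in place of a 0. In the text a fold against a 0 is given as a bound, the lower limit of its exact 95% interval. Entries with at least 50 counts over both columns were evaluated, which left 349 entries with 99.5% of the control and 99.2% of the shWDR4 counts. A 2-fold difference was the size rule.

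The test fixed before the data were examined was edgeR's quasi-likelihood test over 6 libraries, with the rule that no test is run where values per library are lacking. That rule applied, so no p-value was computed here and no count adjusted over a list alone exists. The 20 miRNA lists were fixed before the data were examined. The planned Fisher test of list members against other entries was replaced, because 1 pooled value per group has no replicate error. In its place the median log2 fold of each list with at least 3 evaluated members was ranked among the medians of 10000 random lists of the same size, each member drawn from the same of 10 classes of mean CPM. This percentile describes these pooled columns and is not a test between the conditions. About 5% of lists of unrelated entries would fall outside the central range of percentiles 2.5 to 97.5 by chance. Members that share reads or a hairpin can move together, so for such lists the rate can be higher.

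The entries named in the text follow a rule fixed before the data were examined. It takes the 10 largest folds in each direction among the entries marked in the authors' deposited table, ties included, the 5 entries with the highest mean CPM, and up to 4 members of each list in order of the deposited p-value. For each deposited enrichment table it takes the 5 terms with the smallest p-value. Entries chosen after their values were seen are named as such.

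Hairpin positions come from GENCODE release 29 on GRCh38, matched by miRNA name. Hairpin GC content was had for 339 of the 349 evaluated entries. The prefix for human miRNAs is left out of the names. Scale factors for the alternatives (trimmed mean of M values, median ratio, upper quartile) came from edgeR 4.0.16 in R 4.3.3. Other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Alternatives also changed the minimum count, the background of the random lists, the entry with the highest mean CPM and duplicated entries.

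The procedure was tested on simulated data with the 2 column totals and 200 changed entries. All 91 evaluated entries changed 4-fold and all 95 changed 8-fold were recovered at 2-fold in the right direction (100% each), and 0% of 156 unchanged entries passed the 2-fold rule. The exact intervals held the true fold for 97.1% of 342 entries. The simulation drew counting error only, so it says nothing about the spread between repeats. Its changed entries were not rescaled to the column total and its scale was known. It therefore does not test the shift that scaling to column totals can bring.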

Results

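The series asked how WDR4 takes part in the sorting of miRNAs into exosomes. Exosomal small RNA was sequenced from H1299 lung cancer cells that stably expressed a control or a WDR4 short hairpin RNA, with 3 libraries per group joined into 1 count column each. The control column held 1020282 counts over 906 detected miRNAs, and the shWDR4 column held 552913 counts over 1061. Thinned to the shWDR4 total, the control column would show 862 detected miRNAs, with an SD of 5.35 over draws. Both columns contained 720 miRNAs, 186 were detected in control alone and 341 in shWDR4 alone. The transcript of WDR4 itself is not among the entries, so the knockdown was not checked here. With 1 pooled value per group, no difference below has a replicate check, and each compares the pooled columns rather than the conditions. All libraries are of exosomes and none of whole cells, so changed sorting cannot be told from a changed level in the cells.

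Different miRNAs were most abundant in the 2 groups. In control exosomes let-7a-5p, a growth-restraining miRNA, led with 17.6% of the counts (exact 95% interval 17.5 to 17.6), and miR-16-5p followed with 10.4% (10.3 to 10.4). In shWDR4 exosomes they held 2.98% (2.94 to 3.03) and 3.89% (3.84 to 3.94). There miR-3960 led with 20.6% (20.4 to 20.7), against 0.617% in control (0.602 to 0.633), a 33.3-fold higher CPM (32.5 to 34.2). The entry miR-6126 held 10.2% (10.1 to 10.3) against 0.1002% (0.0941 to 0.107), 102.0-fold higher (95.9 to 108.6). Among the 5 entries with the highest mean CPM, miR-93-5p differed least, with 5.19% in control (5.15 to 5.23) and 3.83% in shWDR4 (3.78 to 3.88).

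Of the 349 evaluated miRNAs, 91 were at least 2-fold higher and 110 at least 2-fold lower in shWDR4, and 148 lay within 2-fold. The median log2 fold of the 349 entries was -0.37 with scaling to the column totals and ranged from -0.75 with upper-quartile scaling to -0.05 without miR-3960. The split moved with it, to 76 higher and 151 lower with upper-quartile scaling and to 102 higher and 79 lower without miR-3960. The 10 largest miRNAs of each column, chosen separately, held 60.1% of the control and 60.4% of the shWDR4 counts. The 2 sets of 10 are not the same miRNAs. Of the 15 miRNA lists that were ranked, 4 had a median outside the central range of random lists, those of let-7, miR-34, mesenchymal and endothelial markers and small RNA overlaps.

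**Figure D1:**
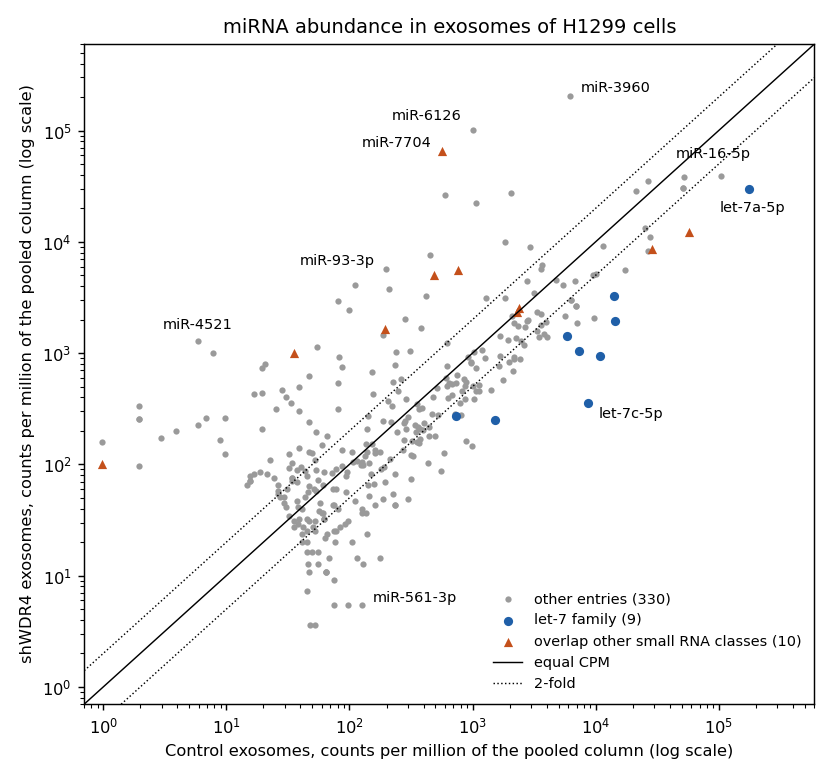
CPM of each pooled column on log axes, control exosomes on the x axis and shWDR4 exosomes on the y axis, 1 point per miRNA with at least 50 counts over both columns and a count of 0 drawn at the level of 3 counts. The 9 let-7 family members (blue) lie below the line of equal CPM, while miR-3960, miR-6126 and miR-7704 lie at 33.3, 102.0 and 116.3 times their control level, and no replicate error can be drawn.

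The let-7 family, which restrains growth and is a known substrate of the METTL1-WDR4 methyltransferase, was lower in shWDR4 exosomes in all 9 members with every scaling tried. Together the members went from 23.9% of the control counts (23.83 to 23.995) to 3.93% of the shWDR4 counts (3.88 to 3.98), a 6.08-fold lower share (5.998 to 6.167). The smallest difference was that of miR-98-5p, named after its value was seen, at 2.69-fold (2.25 to 3.22), and the largest that of let-7c-5p, which went from 8861 to 196 counts, 24.5-fold lower (21.3 to 28.4). Between them lay let-7a-5p at 5.89-fold (5.80 to 5.98), let-7e-5p at 7.37-fold (6.93 to 7.85) and let-7b-5p at 11.5-fold (10.5 to 12.6). The median log2 fold of the family was -2.60 against -0.59 for the middle random list, below all 10000 random lists. The authors' deposited table marked all 9 members as lower in shWDR4. Members differ by few bases, so how reads were divided among them is uncertain, and in that respect the family sum is the firmer value. The sum was taken with scaling to the column totals alone. Upper-quartile scaling shifts every log2 fold by -0.38 and leaving out miR-3960 by 0.32, and either takes the sum outside its counting interval. Together miR-3960, miR-6126 and miR-7704 held 0.774% of the control and 37.3% of the shWDR4 counts. The let-7 sum without all 3 was not computed.

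Hairpins of let-7a lie on chromosome 9 at 94175957 to 94176036, chromosome 11 at 122146522 to 122146593 and chromosome 22 at 46112749 to 46112822 of GRCh38. That of let-7c lies on chromosome 21 at 16539828 to 16539911. The hairpin of miR-3960 lies on chromosome 9 at 127785833 to 127785923, within an exon of CDK9, a kinase of transcription elongation, on the same strand. That of miR-6126 lies on chromosome 16 at 3485381 to 3485469, opposite NAA60, and that of miR-7704 on chromosome 2 at 176188843 to 176188901 in an exon of the homeobox gene HOXD1. Both miR-93 arms come from chromosome 7 at 100093768 to 100093847, inside the replication gene MCM7 and outside its exons. The hairpins of miR-16 lie on chromosome 13 at 50048973 to 50049061 within DLEU2 and on chromosome 3 at 160404745 to 160404825 within SMC4.

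A small family and a cluster had low medians at little depth, the cluster inside the central range of random lists. The p53-responsive miR-34 family had 3 evaluated members, all lower, with a median log2 fold of -2.42 at percentile 2.32 of the random lists. Counts went from 237 to 24 for miR-34c-5p, 141 to 13 for miR-34a-5p and 100 to 17 for miR-449a, while miR-34b-5p had 5 and 0, too few for a fold. The authors' deposited table marked 3 of the 5 measured members as lower. Its percentile was 2.69 without miR-3960, 2.505 with duplicated entries removed and 7.57 against low-numbered entries, inside the central range. The imprinted chromosome 14 cluster had 4 evaluated members, all lower, with a median of -2.03 at percentile 4.45. Of its 15 measured members the authors' deposited table marked 5 as lower and none as higher. Among them miR-432-5p was 10.2-fold lower (4.82 to 25.9), miR-382-5p 3.84-fold (2.03 to 8.01) and miR-376c-3p 4.34-fold (1.85 to 12.4), and miR-379-5p went from 23 to 0, at least 3.12-fold lower. With a minimum of 20 counts its percentile was 1.355, outside the central range, and against low-numbered entries it was 14.975, inside it.

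The cell cycle restraining miR-15/16 family had a median of -1.42 at percentile 5.70, and its members went both ways. The authors' deposited table marked 4 of the 7 members as lower and 1 as higher. Lower values were 2.67-fold for miR-16-5p (2.63 to 2.71), 2.2002-fold for miR-15b-5p (1.93 to 2.51) and 4.23-fold for miR-424-5p (3.05 to 6.01), whereas miR-503-5p was 4.40-fold higher (3.90 to 4.96). The hairpin of miR-503 lies on chromosome X at 134546328 to 134546398.

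The following 5 lists had medians inside the central range. The oncogenic list with miR-21 and miR-221 had a median of -0.91 (percentile 24.4), and the authors' deposited table marked 4 of its 10 members as lower. Among its members miR-155-5p was 3.79-fold lower (3.55 to 4.05), miR-21-5p 2.38-fold (2.15 to 2.64), miR-31-5p 1.88-fold (1.80 to 1.96) and miR-221-3p 1.41-fold (1.32 to 1.502). The miR-320 family had a median of -1.23 (percentile 11.7) with 3 of 4 members marked lower in the authors' deposited table. Its members miR-320b, miR-320c, miR-320d and miR-320a-3p were 2.63-fold (2.47 to 2.80), 2.58-fold (2.39 to 2.78), 2.15-fold (1.93 to 2.40) and 1.93-fold (1.88 to 1.98) lower. Medians were -1.24 for the miR-29 family (percentile 19.9), -1.10 for the miR-181 family (percentile 15.7) and -0.81 for the clusters of miR-23, miR-27 and miR-24 (percentile 33.6). The authors' deposited table marked 2 of 3, 2 of 4 and 1 of 5 of their members as lower. Members with the smallest deposited p-values were miR-29b-3p at 2.37-fold lower (2.15 to 2.61), miR-181a-5p at 2.15-fold (2.00 to 2.32) and miR-27a-3p at 2.34-fold (2.03 to 2.69).

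Smaller differences were seen in 3 further families. The proliferation-linked clusters of miR-17-5p and its paralogs had a median of -0.44 at percentile 48.9, and the authors' deposited table marked 4 of 13 members as lower. There miR-20a-5p was 2.77-fold lower (2.51 to 3.06), miR-17-5p 2.23-fold (1.77 to 2.82) and miR-18a-5p 2.205-fold (1.74 to 2.82), and miR-93-5p 1.36-fold (1.33 to 1.38). The miR-30 family had a median of -0.38 at percentile 55.7, with 1 of 7 members, miR-30e-3p, marked lower in the authors' deposited table, at 2.46-fold (2.28 to 2.67). The miR-99/100 and miR-125 family had a median of -0.19 at percentile 68.4, which became 0.13 without miR-3960. The authors' deposited table marked none of its 5 members, of which 4 were lower and 1 higher with scaling to the totals. The higher one, miR-100-5p, took 2.12% of the control counts (2.09 to 2.14) and 2.84% of the shWDR4 counts (2.79 to 2.88). With upper-quartile scaling its log2 fold was 0.04.

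Some fixed lists were too thin to rank. Both measured members of the epithelial miR-200 family were unmarked in the authors' deposited table, with 34 and 7 counts for miR-200c-3p and 11 and 0 for miR-141-3p. None of the 7 measured members of the placental chromosome 19 cluster was marked in the authors' deposited table, and their counts summed to 45 in control and 11 in shWDR4. No member of the embryonic cluster of miR-371a was among the entries. A further list was fixed under the heading of GGAG-motif miRNAs reported in exosome sorting, and the motif was not checked in the sequences. Of its 5 members, 2 were measured. One of them, miR-887-3p, had 102 counts in control and 1344 in shWDR4, 24.3-fold higher (19.9 to 30.0), and was marked higher in the authors' deposited table. The other, miR-451a, had 0 and 3 counts.

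The list fixed for overlap with other classes of small RNA, such as ribosomal or transfer RNA, had a median log2 fold of 2.98 at percentile 99.9. The middle random list had -0.53. Overlap of the members with such RNA was not checked here. The authors' deposited table marked 6 of the 11 measured members as higher and 2 as lower. In this list miR-7704 went from 576 to 36296 counts, 116.3-fold higher (107.1 to 126.5), and miR-619-5p was 10.4-fold higher (9.45 to 11.5). By contrast miR-1290 was 4.67-fold lower (4.55 to 4.79) and miR-1246 3.32-fold lower (3.22 to 3.42), and the summed share of the list was 9.30% (9.24 to 9.36) in control and 10.5% (10.4 to 10.6) in shWDR4. Most members carry high numbers, and the list had too few low-numbered members to be ranked against low-numbered entries.

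Several markers of other cell types were lower in shWDR4 exosomes beside the let-7 family, and others could not be told from no difference. The mesenchymal and endothelial list had a median of -2.43 at percentile 0.755, with 3 of 7 members marked lower in the authors' deposited table. These were the endothelial miR-126-3p, from 9954 to 1153 counts and 4.68-fold lower (4.40 to 4.98), miR-126-5p at 5.41-fold (4.35 to 6.79) and the smooth muscle miR-143-3p at 6.76-fold (5.38 to 8.58). Both miR-126 entries come from the same hairpin. The percentile was 2.585 against low-numbered entries and 2.805 with a minimum of 200 counts, inside the central range. The blood cell list had a median of -1.46 at percentile 8.46, inside the central range. With a minimum of 20 counts it had 5 members and a median of -0.78 at percentile 23.7. The authors' deposited table marked 2 of its 7 members as lower, the red cell miR-486-5p at 2.76-fold (2.22 to 3.45) and the leukocyte miR-142-3p from 100 to 3 counts, 18.1-fold (6.01 to 89.1). The intervals of 2 unmarked members included no difference, those of miR-142-5p, with 54 and 17 counts and a fold of 0.581 (0.316 to 1.02), and miR-150-5p, with 24 and 18 counts and a fold of 1.38 (0.708 to 2.66). Of the liver and muscle list only miR-122-5p, made in hepatocytes, was evaluated, at 3.12-fold lower (2.80 to 3.49). The authors' deposited table marked it and miR-499a-5p, with 34 and 2 counts, as lower. The muscle miR-1-3p, with 6 and 3 counts, had a fold of 0.923 (0.149 to 4.32).

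**Figure D2:**
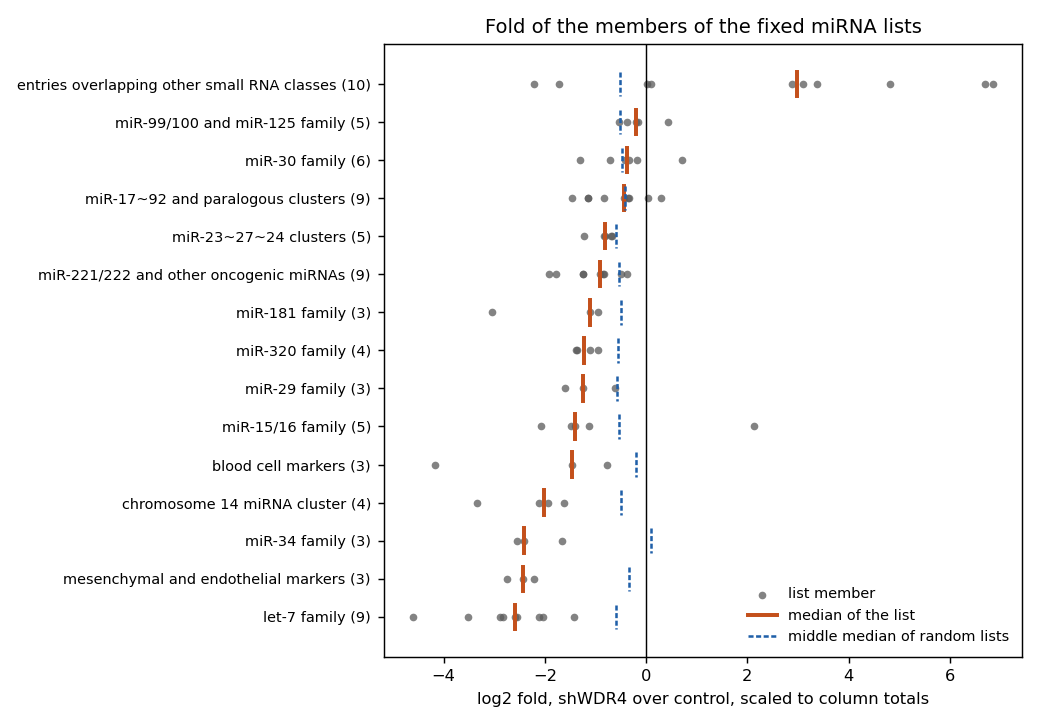
Log2 fold of shWDR4 over control (x axis) for the members of each of the 15 ranked lists with at least 50 counts (grey points, number in brackets), with the list median (orange bar) and the middle median of 10000 random lists matched on mean CPM (blue dashed bar). The let-7 median lies at -2.60 and that of the list fixed for overlap with other small RNA classes at 2.98. Points carry no replicate error.

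The entries that rank first by the fold of the authors' deposited table, which sets a 0 to 0.5, were mostly near the floor in a column. On the higher side, in the order of the authors' deposited table, these began with miR-765, from 0 to 96 counts and at least 47.1-fold higher. Next came miR-4521, from 6 to 704 counts and 216.5-fold higher (99.0 to 592.0). The 10 also held miR-1469 with 2 and 184 counts (169.8-fold, 46.3 to 1412), miR-4443 with 1 and 87 (160.5-fold, 28.1 to 6413) and miR-6892-5p with 8 and 550 (126.9-fold, 63.9 to 295.3). The pair miR-10396a-5p and miR-10396b-5p had identical counts of 2 and 141, so how their reads were divided is uncertain. Counts went from 0 to 40, 34 and 33 for miR-937-5p, miR-6825-3p and miR-6727-5p, at least 19.1-fold, 16.1-fold and 15.6-fold higher. These bounds lie below the folds of the abundant miR-7704 (116.3) and miR-6126 (102.0), so the order reflects the value set for a 0. The hairpin of miR-765 lies on chromosome 1 at 156936131 to 156936244 within ARHGEF11, and that of miR-4521 on chromosome 17 at 8186945 to 8187004.

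On the lower side of the same order let-7c-5p and miR-561-3p, which had 129 and 3 counts (23.3-fold, 7.80 to 114.5), were the only ones of the 11 with reads in shWDR4. The other 9 had between 20 and 24 control counts and 0 in shWDR4, which shows a difference of at least 2.68-fold to at least 3.26-fold. Such bounds cannot rank them against the 18.1-fold of miR-142-3p or the 11.5-fold of let-7b-5p. These 9 entries were miR-20b-5p, miR-379-5p, miR-4723-3p, miR-6867-5p, miR-3177-3p, miR-3192-5p, miR-6741-3p, miR-10399-3p and miR-3145-3p. Among abundant entries chosen after their values were seen, miR-4787-5p was 44.1-fold higher (40.7 to 47.9), miR-4634 21.1-fold (19.8 to 22.5) and miR-1275 13.4-fold (12.77 to 14.01).

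The authors' deposited table marked 327 of its 1247 miRNAs, 192 as higher and 135 as lower in shWDR4. In counts, the 135 miRNAs that the authors' deposited table marked as lower took 61.1% of the control column and 16.5% of the shWDR4 column. The 192 marked as higher in the authors' deposited table took 2.499% and 54.5%. Of the 327 marked entries in the authors' deposited table, 130 had under 50 counts over both columns, 57 were at 0 in control and 15 at 0 in shWDR4. A further 64 entries of the authors' deposited table passed the q-value threshold with less than a 2-fold difference, 49 lower and 15 higher. With at least 50 counts required, 90 entries marked higher and 107 marked lower were left in the authors' deposited table.

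The authors' deposited table of Gene Ontology terms listed 11 biological processes for 111 annotated genes, and stem cell and neural terms came first. The smallest p-value in the authors' deposited table was that of stem cell population maintenance, with 10 genes (p = 3.30e-08, adjusted p = 4.20e-05), among them NOTCH2, LIN28A and PRDM16. LIN28A encodes a protein that blocks let-7 maturation. The same 10 genes gave maintenance of cell number in the authors' deposited table (p = 3.72e-08). Negative regulation of nervous system development (11 genes, p = 2.80e-06), of gliogenesis (5 genes, p = 6.86e-06) and of neurogenesis (10 genes, p = 1.05e-05) followed in the authors' deposited table.

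For 38 annotated genes, the authors' deposited table of KEGG pathways listed 9, of which 6 had an adjusted p-value under 0.05. The first 5 in the authors' deposited table were Fc gamma R-mediated phagocytosis (5 genes, p = 0.000322), VEGF signaling (4 genes, p = 0.00135), toxoplasmosis (5 genes, p = 0.00150), small cell lung cancer (4 genes, p = 0.00205) and progesterone-mediated oocyte maturation (4 genes, p = 0.00223). The phosphoinositide kinase subunit PIK3R3 was in each of these 5 pathways of the authors' deposited table. All 39 distinct genes named in both kinds of deposited table lie on chromosome 1, where 10.3% of protein-coding genes lie and 4.01 would be placed by that share.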

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

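The trimmed-mean scaling, the minimum counts of 20 and 200, the removal of duplicated entries, the replacement of 0 by 0.5, the count of marked entries with at least 50 counts and all alternatives for the list ranks were chosen after the data were seen. No paired analysis was possible because each group is 1 pooled column without replicate numbers. Leaving out replicates, the block, other tests (DESeq2, the exact test, limma, camera with an estimated correlation, fry), the CPM filter over libraries, the similarity of libraries and other splits of the samples were not run for the same reason. Pseudocounts other than the 0.5 given below were not run. The 2-fold counts of 91 higher and 110 lower became 151 and 154 with a minimum of 20 counts, and 48 and 68 with 200, where more or fewer entries were evaluated. With no minimum they were 339 and 219, and 315 and 310 where 0.5 also replaced the 3 counts set for a 0. They stayed within 1.5 times under the other 5 settings, from 76 to 102 higher and 79 to 151 lower. Another scaling shifts every log2 fold by the same amount, so the ranks of the lists could not change and 4 stayed outside the central range. The number became 5 with a minimum of 20 counts, 3 without miR-3960 and 3 without duplicated entries. It was 2 with a minimum of 200 counts, where miR-34 is not rankable. With entries numbered below 1000 as background 1 was left, let-7, and the list of small RNA overlaps is not rankable. In the authors' deposited table, 192 higher and 135 lower became 271 and 199 with a Benjamini-Hochberg q-value under 0.05 and 2-fold, 294 and 263 with that q-value alone, and 309 and 304 with an unadjusted p-value under 0.05. The first of these changed the kind of q-value and its limit, the others also dropped the 2-fold rule, and the cause was not tested. With at least 50 counts 90 marked higher were left. KEGG pathways in the authors' deposited table numbered 4 with at least 5 genes, against 9. Of 306 alternative values of named entries, 166 stayed within their counting interval, 140 moved outside it and no marked entry changed sign. Of 114 alternative list medians 72 stayed within it and 42 moved. The let-7 median ranged from -2.98 to -2.28. Depth limits entries near the floor of 2.94 CPM in control and 5.43 CPM in shWDR4.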

Other observations

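In this part the tests of scaling, of serum carry-over, of counting error and of the chromosome of the enrichment genes were chosen after the results were seen. The comparison of arms was also made after the values were seen. The arms of a hairpin, its 5p and 3p products, did not always move together in shWDR4 exosomes. Of 51 hairpins with both arms evaluated, the arms lay within 1 log2 unit of each other in 33, and the log2 folds had opposite signs in 13 with scaling to the totals. For miR-93, from a cluster linked to proliferation, the 5p arm was 1.36-fold lower while the 3p arm went from 201 to 3169 counts, 29.1-fold higher (25.2 to 33.7). For miR-23a the 3p arm was 1.61-fold lower (1.41 to 1.84) while the 5p arm went from 17 to 236 counts, 25.6-fold higher (15.7 to 44.7). In miR-197 the 5p arm was 11.2-fold higher (8.86 to 14.3) beside a 3p fold of 0.816 (0.706 to 0.941). The 5p arm lay higher by over 2 log2 units in 8 hairpins and the 3p arm in 4.

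Entries with high numbers, which miRNA naming assigns to later discoveries, were on the whole higher in shWDR4. The 137 evaluated entries numbered 1000 or above had a median log2 fold of 0.88 and went from 20.5% to 60.4% of the counts, and the 212 others had a median of -0.84 and went from 79.1% to 38.8%. Most of the gain in share belonged to miR-3960, miR-6126 and miR-7704, picked by their gain, which together went from 0.774% to 37.3%, while the other 134 high-numbered entries went from 19.7% (19.6 to 19.8) to 23.1% (22.97 to 23.2) with a median of 0.82. Across entries, which are not independent replicates, hairpin GC content and log2 fold had a Spearman rho of 0.44. Some pairs of entries on opposite strands of a locus had identical counts, so reads were given to both entries of such a pair. An example, chosen after its values were seen, is miR-423-5p and miR-3184-3p with 52349 and 16692. Opposite-strand pairs were sought only among entries with identical counts. The other arms of that locus differed, with 350 and 126 counts for miR-423-3p and 217 and 62 for miR-3184-5p.

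Lower let-7 in shWDR4 exosomes is the first pattern weighed. With trimmed-mean scaling the family median was -2.44. This value cannot decide on the choice of scaling, because any scaling shifts every log2 fold by the same amount, here by 0.16. How far let-7 fell in absolute amount is therefore not shown. Such a shift does not change the distance of the family median from the middle random list, -2.60 against -0.59 with scaling to the column totals. Set against entries within 5 percentage points of hairpin GC the median difference was -1.81 (SD over the 9 members 1.02, 8 members below by over 1). This argues against GC content of the hairpin, while that of the counted mature miRNA was not measured here. Carry-over from serum cannot be told apart, although the labels name medium freed of exosomes, since the let-7 median differed by -0.37 from that of the 7 blood, liver, mesenchymal and endothelial markers with at least 50 counts, whose values lay below 0 with an SD of 1.09, although the interval of miR-142-5p included no difference and the thinner miR-150-5p had a fold of 1.38. Whether H1299 cells make these marker miRNAs was not measured here. The hypothesis that WDR4 loss lowers let-7 in exosomes may hold, but it and a difference between cultures or libraries of the groups stay open, untested, with the repeats pooled. Without cellular libraries, changed sorting of let-7 cannot be told from a changed level in the cells.

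The higher level of high-numbered and GC-rich entries in shWDR4 is the second pattern. The share of counts in high-numbered entries, 60.4% in shWDR4 (60.3 to 60.5) and 20.5% in control (20.4 to 20.5), argues against counting error at these depths, as do the values without the 3 entries of largest gain, whereas thinning the control column, after which 96.7% of the 91 entries at least 2-fold higher stayed so, leaves expected ratios as they are and decides nothing. At 40 to 60% hairpin GC the median of 55 high-numbered entries lay 1.83 log2 units above that of 143 low-numbered ones (resampled interval 0.90 to 2.47), which argues against hairpin GC as the whole cause. Fragments of longer transcripts, possibly counted as miRNA, cannot be told apart, because the hairpin lies in a same-strand exon of another gene for 26 of the 86 entries at least 2-fold higher with a located hairpin (30.2%, 20.8 to 41.1) and 52 of 253 others (20.6%, 15.7 to 26.1), and the intervals overlap. Exons on the opposite strand were not counted, although some opposite-strand pairs of entries had identical counts. A change by WDR4 loss in what enters exosomes stays open and untested.

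The third pattern is the single chromosome of the enrichment genes. Of the 39 distinct genes, 100% (91.0 to 100) lie on chromosome 1, against 10.3% of protein-coding genes. A gene list limited to that chromosome before the enrichment would give this value. The value restates the pattern, however, and is no separate test of such a limit. Whether and where such a limit arose is not shown. No biological explanation was tested.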
